A study of Mus musculus with 16 samples.

How the data were processed

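Placentas from mouse fetuses of 4 genotypes at 18.5 days post coitum were profiled by RNA-seq, with 4 libraries per genotype: wild type (wt), SRC-1 knockout (src1ko), SRC-2 knockout (src2ko) and the knockout of both (dko). Per the labels' protocols, total RNA was extracted with Trizol and libraries were made from 2 μg of RNA with a NEBNext Ultra kit, which does not mark the strand a transcript came from. Per the submitters' processing notes, the tools were HISAT2 2.2.1, featureCounts 2.0.1, R 4.2.1 and DESeq2 1.34.0 with the GRCm38 genome build; the notes give no role or order for them. The settings of alignment and counting, and any trimming, are not given in the sources used here.

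The authors deposited 1 table of 27658 genes by 16 libraries. Its name calls the values FPKM, but the deposited values are treated here as raw counts of reads per gene, for reasons taken from the values. Of them, 0 are not whole numbers, between 1913 and 2293 genes per library stand at exactly 1, and the Spearman correlation of a gene's mean value with its exon length is 0.27, whereas FPKM divides by length. Library sums run from 15595714 to 18520635, while FPKM values for whole libraries have no such totals in reads. The plan fixed before the data were examined assumed FPKM scaled by median-of-ratios size factors and a limma-trend test on log2 values with a pseudocount of 1. Counts need a count test, so edgeR with another scaling was used in its place. The groups, contrasts, threshold and filter value stayed the same. All 16 columns matched the label of 1 sample each. Symbols were matched to GENCODE vM21 on GRCm38 for coordinates, and 26003 symbols (94.0%) matched. Spreadsheet software had turned 15 symbols into dates in the deposited file, 13 of them among the tested genes; these were tested but are not named.

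Genes with at least 1 CPM (read counts scaled to a library size of 1000000) in at least 4 of the 16 libraries were kept, which left 15051 genes. Libraries were scaled by trimmed mean of M-values (TMM) and fitted in 1 model with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, 12 residual degrees of freedom shared by the 4 genotypes, prior degrees of freedom 3.36, common biological coefficient of variation 0.248). All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested in a contrast. A gene was called changed at an adjusted p below 0.05. The contrasts were each knockout against wt, dko against each single knockout, src2ko against src1ko, and the interaction, which is dko minus src1ko set against src2ko minus wt. Levels are TMM-scaled CPM with the SD over n = 4 libraries. Fold changes are log2 values from the edgeR model. Standard errors (SE) were derived from the test, as the absolute log2 fold change divided by the square root of its F statistic.

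Gene lists were written from textbook knowledge before the data were examined: 42 lists of pathways, placental gene families and cell type markers, of which 41 had at least 5 tested members. Each was tested against all other genes with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 41 lists of a contrast. The same test with a correlation estimated from the data, and fry, which tests whether a list's genes move one way on balance without comparing them with other genes, were run beside it. Members passing the gene test were counted over all genes and adjusted over the list alone.

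The genes to be named were also fixed by a rule before the data were examined. It took the targeted family Ncoa1, Ncoa2 and Ncoa3. It then took up to 10 rises and 10 falls with the largest log2 fold change among called genes with at least 2 CPM in the higher group and no overlap between the 4 and 4 libraries, leaving out clone names, Y-linked genes and Xist. From each list past its threshold, or with at least 3 changed members, it took the up to 4 members with the smallest p. Where no gene passed, 3 rises and 3 falls with the smallest p were taken. Genes named outside the rule are said to have been chosen after their values were seen.

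The 3 comparisons against wt share their controls. Correlations and covariances were set beside 20 simulations of unchanged groups against the same 4 wt libraries, overlaps of calls beside the overlap of independent lists, and both beside values from the wt libraries split into pairs. Single-value comparisons used exact permutation tests, and relations across the 16 libraries used 100000 resamples.

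The same steps were tested on simulated counts drawn from the libraries' means and sizes over the 15051 genes. In them 100 genes were changed 2-fold and 100 by a log2 value of 2, all picked from genes with a mean of at least 2 CPM. The edgeR test recovered 68% of the 2-fold changes for src1ko against wt, 70% for src2ko against wt and 69% for dko against wt, and 97%, 95% and 92% of the larger ones. False calls numbered 11 of 178, 10 of 176 and 6 of 170. The list raised in the simulation passed in each of these comparisons and 0 of the other lists did. Each gene was drawn independently, so the simulation cannot test camera's preset correlation for lists whose genes move together. Recovery holds for this number of changed genes and may be lower where fewer genes change. It was not measured for genes with a mean below 2 CPM, where it may also be lower.

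Alternatives planned before the data were examined were scaling by library totals or by TPM totals, quantile normalization, pseudocounts of 0.1 and 0.5 with limma-trend, no filter on low counts, a mean of at least 5 CPM, a robust variance estimate, library weights, a fit of the contrasted groups alone, the replicate number as a block, covariates for Y-linked genes and for decidua markers, a 2-fold threshold, and leaving out each of the 16 libraries in turn. Library weights were fitted with limma (voom) and quantile normalization with limma-trend, so both also replaced the edgeR test. Median-of-ratios size factors and limma-trend with a pseudocount of 1 were parts of the planned main test and became alternatives once edgeR had replaced it. Added after the data were seen were DESeq2 1.42.0, a yolk sac covariate, comparisons sharing no library, and leaving out src2ko libraries 1 and 4. No sample was left out of the results reported first.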

Results

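Steroid receptor coactivators SRC-1 and SRC-2 bind nuclear receptors and raise transcription of their target genes. The data address how placental transcripts near term differ when SRC-1, SRC-2 or both are missing. Placentas of wild-type (wt), SRC-1 knockout (src1ko), SRC-2 knockout (src2ko) and double knockout (dko) fetuses were sampled at 18.5 days post coitum, with 4 libraries per genotype. Between 15595714 and 18520635 reads per library were counted to genes. The range was 16042682 to 18309243 in wt, 17118990 to 17941921 in src1ko, 15595714 to 18092491 in src2ko and 17756255 to 18520635 in dko. The labels do not say whether the 4 placentas of a genotype came from separate litters, so p-values measure only the spread between these libraries. Litter, fetal sex and maternal genotype are not given in the sources used here.

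The targeted transcripts were lower in the genotypes labelled as lacking them, and both remained detectable. Ncoa2, which encodes SRC-2 (chromosome 1, 13139105 to 13374083, GRCm38, GENCODE vM21), averaged 156.2 ± 15.1 CPM in wt and 160.2 ± 21.2 CPM in src1ko (SD, n = 4). It averaged 39.4 ± 5.86 CPM in src2ko, 25.2% of wt, and 40.8 ± 2.45 CPM in dko, 26.1% of wt. Both falls passed the edgeR quasi-likelihood test (adjusted p = 5e-07 and 7e-07). Each of the 8 src2ko and dko libraries lay between 31 and 44.25 CPM, below the lowest wt library at 139.6 CPM. Ncoa1, which encodes SRC-1 (chromosome 12, 4247362 to 4477182), averaged 9.71 ± 2.39 CPM in wt and 8.23 ± 1.73 CPM in src2ko. It averaged 4.51 ± 1.53 CPM in src1ko, 46.4% of wt, and 3.86 ± 0.853 CPM in dko, 39.7% of wt. The src1ko libraries (2.94 to 6.61 CPM) and the wt libraries (7.27 to 12.6 CPM) did not overlap. Adjusted over the 3 family members the difference passed (p = 0.00132; exact permutation p = 0.0286, the smallest that 4 against 4 can give), but over all genes the adjusted p was 0.983. In dko the fall in Ncoa1 passed over all genes (adjusted p = 0.0183). The related gene Ncoa3 (chromosome 2, 165992636 to 166073242) averaged 106 ± 23 CPM in wt, 98.1 ± 14.7 CPM in src1ko, 74.2 ± 23.8 CPM in src2ko and 106.3 ± 18.4 CPM in dko. Over all genes no genotype passed against wt (src2ko, log2 fold change -0.51, adjusted p = 0.19). Adjusted over the 3 family members src2ko passed (p = 0.0445), but its libraries (46.8 to 94.9 CPM) overlapped with wt (88.0 to 138.3 CPM; exact permutation p = 0.171). Exons outside a deleted part can still give reads, so these levels check the labels and do not measure the protein. Ncoa3 overlaps Sulf2, and reads from the pair cannot be told apart without strand.

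**Figure D1:**
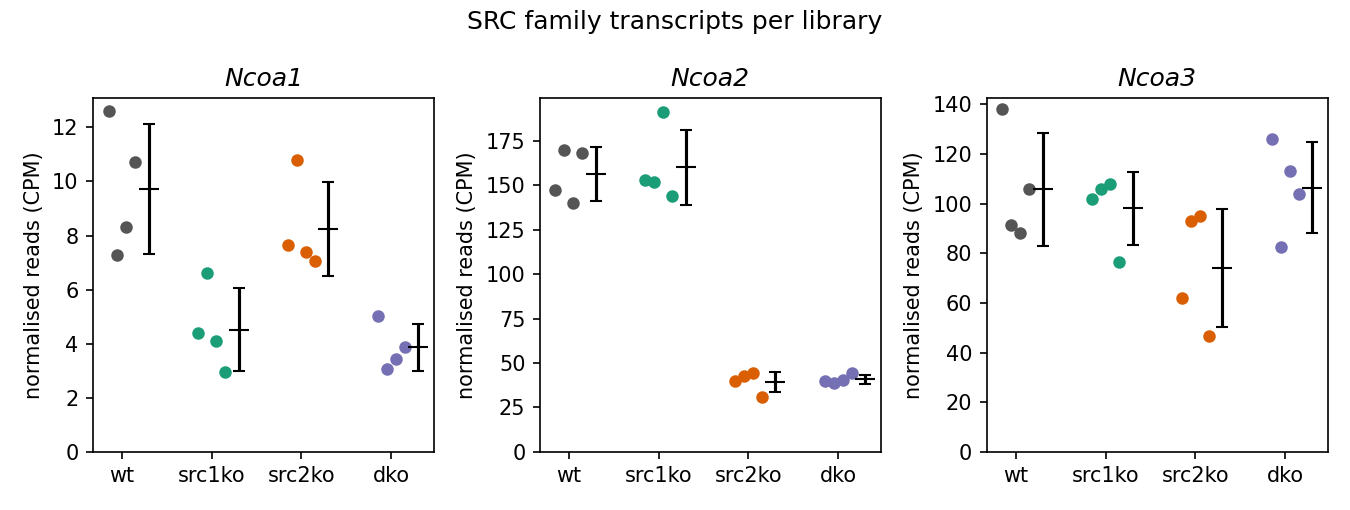
Normalised reads (CPM, vertical axis) of Ncoa1, Ncoa2 and Ncoa3 in each of the 16 libraries, by genotype; points are libraries and bars the mean with its SD (n = 4). Ncoa2 lies between 31 and 44.25 CPM in src2ko and dko, against 139.6 CPM or more in wt.

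Markers of tissues other than the fetal placenta differed between libraries of 1 genotype. The sum of 4 Y-linked genes stood at 111 to 190 CPM in 7 libraries (2 of wt, 1 of src1ko, 3 of src2ko and 1 of dko) and at 0 to 1.04 CPM in the other 9. Xist, the transcript of the inactive X chromosome in females, stood at 718 to 1047 CPM in the 9 libraries low in Y-linked reads and at 1.25 to 7.54 CPM in 5 of the 7 high in them. The other 2, src2ko libraries 1 and 4, held Y-linked reads at 141 and 117 CPM together with Xist at 34.5 and 94.8 CPM, 4% and 11% of the median of the libraries low in Y-linked reads. The same pair held the most Prl8a2, a prolactin-family hormone of the maternal decidua, at 165 and 928 CPM against 1.74 to 58.9 CPM in the other 14 libraries. Yolk sac endoderm markers spanned a wide range within every genotype. Afp, the main serum protein made by yolk sac, ran from 27.4 CPM in dko library 1 to 20830 CPM in dko library 2, and the apolipoprotein gene Apoa1 from 4.43 to 4018 CPM. Xist, Prl8a2, Afp and Apoa1 were chosen after their values were seen. On a principal component analysis, the first component held 26.5% and the next 20.1% of the variance, and src2ko libraries 1 and 4 stood together at one end of the latter (-56.9 and -56.8).

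**Figure D2:**
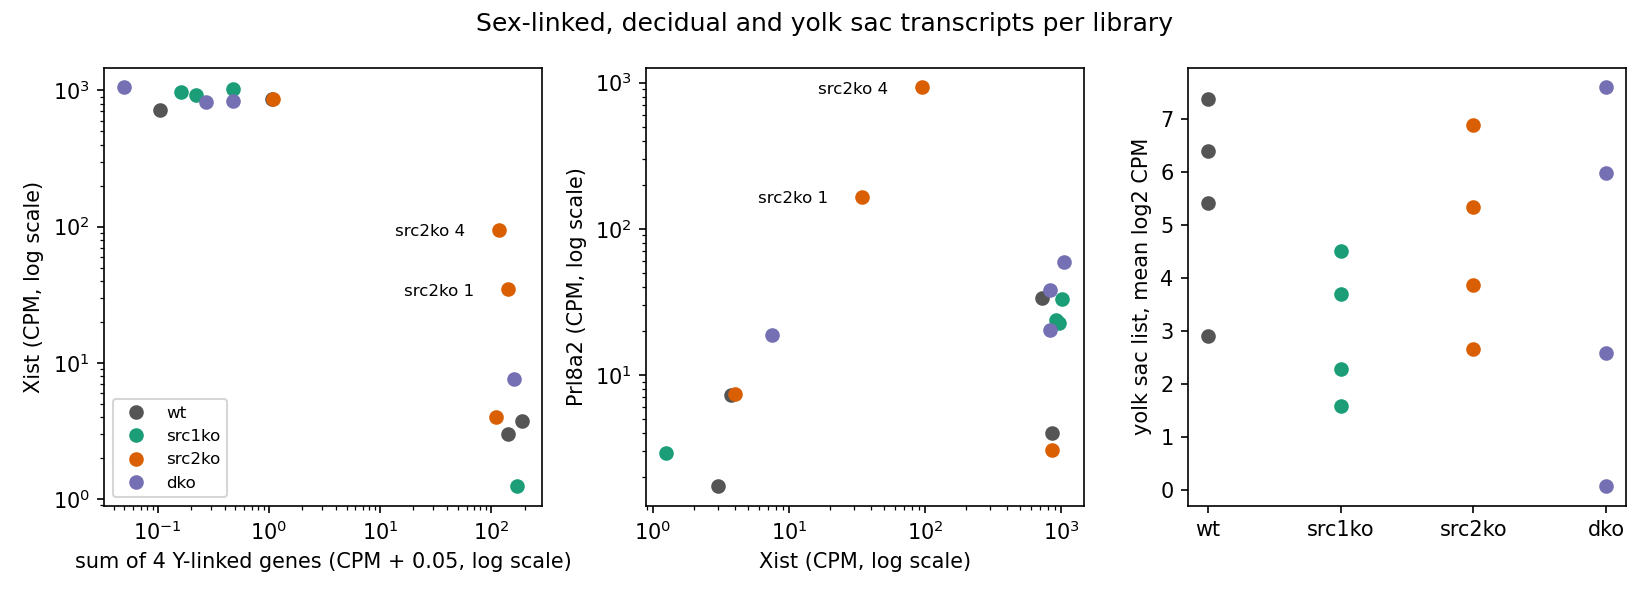
Each point is 1 library, coloured by genotype. Left, Xist against the sum of 4 Y-linked genes; middle, Prl8a2 against Xist (CPM, log scales); right, the mean log2 CPM of the yolk sac endoderm markers. The src2ko libraries 1 and 4 hold Y-linked reads at 141 and 117 CPM, Xist at 34.5 and 94.8 CPM and the most Prl8a2.

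Between src1ko and wt not a single gene was called. The transcript nearest to a call was Prl7a2, a placental prolactin-family hormone (chromosome 13, 27658584 to 27668036), at 953.2 ± 330.0 CPM in wt and 1981 ± 367 CPM in src1ko, a log2 fold change of 1.06 (SE 0.221, n = 4) with an adjusted p of 0.983. The other genes with the smallest p, none of which passed, were Arhgap39 (0.46) and Cilp2 (0.67) among those higher, and Ncoa1 (-1.11), Mindy3 (-0.40) and Ctps2 (-0.32) among those lower. The edgeR test called 0 of 15051 genes, with 760 at an unadjusted p below 0.05, and DESeq2 called 1, Prl7a2. Leaving out any of the 16 libraries gave 0 called genes as well.

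Gene lists in src1ko passed camera only with a preset correlation between genes, and 0 passed fry. Of the 41 lists, 16 passed camera with a preset correlation and 0 with an estimated correlation, for which the lowest adjusted p was 0.44. Over 8 alternatives the adjusted p of these 16 lists ran from 2.5e-19 to 0.682. All 24 tested genes of cholesterol synthesis, which make sterols and steroid precursors, were lower in src1ko than in wt by point estimate (median log2 fold change -0.39). Of them 0 rose or fell over all genes or adjusted over the list alone (camera adjusted p = 3.66e-07; adjusted p = 0.55 with an estimated correlation). All 21 tested yolk sac endoderm markers were lower too, with a median of -2.9 and again 0 members passing (adjusted p = 3.46e-17; 0.51 with an estimated correlation). The placental prolactin family was higher (median 0.24 over 23 genes, adjusted p = 6.67e-06; 0.51 with an estimated correlation), and 2 members, Prl7a2 and Prl8a1, passed when adjusted over the list alone. Spongiotrophoblast markers (median 0.28 over 15 genes) and proliferation genes (median 0.23 over 24 genes) were higher with 0 members passing (adjusted p = 2.39e-06 and 8.23e-07; 0.51 and 0.44 with an estimated correlation). Markers of other cell types shifted too, again with 0 members passing: all 13 erythroid markers (median 0.61), 16 of 18 endothelial (0.25) and 13 of 16 macrophage markers (0.36) were higher (adjusted p = 5.33e-05, 0.000221 and 0.00139; 0.52, 0.57 and 0.51 with an estimated correlation). All 13 mitochondrial transcripts were lower (median -0.27, adjusted p = 0.000181; 0.58 with an estimated correlation).

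Between src2ko and wt 654 genes differed, 466 higher and 188 lower in src2ko. Among the falls were Ceacam-ps1, a transcribed pseudogene of the pregnancy-specific glycoprotein relatives (chromosome 7, 16648949 to 16657476), at 8.05 ± 4.11 CPM against 72.4 ± 28.0 CPM in wt (n = 4). Il21r, which encodes a cytokine receptor chain (chromosome 7, 125603429 to 125633570), stood at 3.25 ± 1.18 against 18.8 ± 8.56 CPM. Htr1d, a serotonin receptor gene (chromosome 4, 136423524 to 136444398), fell from 29.7 ± 10.9 to 7.71 ± 1.99 CPM, and Ube2ql1, a member of the ubiquitin-conjugating enzyme family (chromosome 13, 69702832 to 69739889), from 8.45 ± 3.0 to 1.51 ± 0.372 CPM. Among the rises were Prl7a2, at 3202 ± 535 CPM against 953.2 ± 330.0 CPM (log2 fold change 1.75). Ptger3, a prostaglandin E receptor gene (chromosome 3, 157566892 to 157645888), stood at 85.4 ± 27.8 against 20.5 ± 10.5 CPM. The matrix metalloproteinase genes Mmp10 (chromosome 9, 7502352 to 7510240) and Mmp12 (chromosome 9, 7344381 to 7369499) stood at 3.45 ± 1.87 against 0.399 ± 0.178 CPM and 47.0 ± 24.2 against 6.41 ± 3.76 CPM.

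Rankings by size here and in the other comparisons cover called genes with at least 2 CPM in the higher group and no overlap between the libraries compared, so a larger change outside these limits is not ranked. Within them, the log2 fold changes of the largest falls in src2ko were -3.17 for Ceacam-ps1 (SE 0.442, adjusted p = 0.00162), -2.78 for the secreted Wnt ligand Wnt10b (adjusted p = 0.0146), -2.54 for Il21r (SE 0.374, adjusted p = 0.00201), -2.52 for Zfyve28 (adjusted p = 0.0039) and -2.48 for Ube2ql1 (SE 0.362, adjusted p = 0.00196). They were followed by Il23r, another cytokine receptor gene (-2.25), the potassium channel gene Kcnj5 (-2.08), Chn1os3 (-2.03, adjusted p = 0.00177), Ncoa2 (-1.99) and Htr1d (-1.95, adjusted p = 0.00652). Chn1os3 lies antisense to Chn1, which was chosen after its values were seen and stood at 2.98 ± 0.238 CPM against 6.75 ± 2.01 CPM in wt, and without strand the pair's reads cannot be told apart. Within the same limits, the largest rises were Stac2 (3.65, adjusted p = 0.0179), Mmp10 (3.10, adjusted p = 0.00292), the chemokine gene Cxcl14 (3.07, adjusted p = 0.0348), Mmp12 (2.87, adjusted p = 0.00397) and the potassium channel gene Kcnq2 (2.80, adjusted p = 0.00234). Next came Scand1 (2.71), the asparaginase gene Aspg (2.67), Ptger3 (2.06, adjusted p = 0.00162), the mast cell chymase gene Cma1 (2.02) and Pappa, a protease gene of the insulin-like growth factor system (2.01). Scand1 overlaps Cnbd2 and Mmp12 overlaps Mmp1b, so their reads may be shared. Reads may also be shared among close paralogs of the prolactin and glycoprotein families. Several rises rested on the libraries rich in Prl8a2. Stac2 stood at 8.03 and 21.3 CPM in src2ko libraries 1 and 4 against 1.04 and 1.16 CPM in the other 2. Cxcl14 stood at 4.21 and 22.8 against 1.33 and 1.345 CPM, and Aspg at 15.9 and 48.1 against 4.1 and 3.91 CPM.

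The spongiotrophoblast, the endocrine layer of the mouse placenta, stood out among the lists in src2ko. Of its 15 tested markers 4 rose (Prl8a8 1.07, Psg18 1.10, Flt1 1.03 and Psg19 0.79), 0 fell and 11 did not pass, with 10 rising adjusted over the list alone (camera adjusted p = 1.2e-10; adjusted p = 0.56 with an estimated correlation). Of 20 pregnancy-specific glycoprotein genes 6 rose, among them Ceacam12 (1.33), Ceacam14 (1.13) and Ceacam13 (0.95), 1 fell (Ceacam15, -1.69) and 13 did not pass. Adjusted over the list alone 12 rose and 2 fell (adjusted p = 1.2e-10; 0.56 with an estimated correlation). Of 23 genes of the placental prolactin family 5 rose, Prl7a2, Prl8a8, Prl4a1 (1.43), Prl8a1 and Prl2c5 (0.52, adjusted p = 0.048, lost under 27 of 34 alternatives), while Prl5a1 fell by 1.42. Ceacam15 and Prl2c5 were chosen after their values were seen. Adjusted over the list alone 9 rose and 1 fell (adjusted p = 2.39e-05; 0.56 with an estimated correlation). In the unfolded protein response 4 of 20 rose, with 6 adjusted over the list alone. Calr and Pdia6, which fold proteins in the endoplasmic reticulum, rose by 0.87 and 0.58 and the stress-induced genes Trib3 and Sesn2 by 1.14 and 0.60 (adjusted p = 5.95e-08; 0.56 with an estimated correlation). Of the spongiotrophoblast markers 12 also stand in another list. All 4 lists passed camera again, with a preset correlation, without src2ko libraries 1 and 4. The mean log2 CPM of the prolactin family was 8.457, 7.668, 7.448 and 8.324 in src2ko libraries 1 to 4 (wt 7.051 to 7.867). That of the unfolded protein response was 7.779, 7.304, 7.283 and 7.645 (wt 6.844 to 7.323). For these 2 lists, src2ko libraries 2 and 3 lay within the wt range. The spongiotrophoblast and glycoprotein lists had every src2ko library above wt (at least 10.17 and 10.45 against at most 10.08 and 10.38). Endothelial markers (15 of 18 lower, median -0.31) and mitochondrial transcripts (all 13 lower, median -0.22) moved the other way with 0 members passing either way (adjusted p = 0.0249 and 0.0329; 0.77 for both with an estimated correlation). The SRC family and its partners passed with 1 fall, Ncoa2, among 15 (adjusted p = 0.00513; 0.56 with an estimated correlation).

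Whether other lists passed in src2ko depended on src2ko libraries 1 and 4. All 8 natural killer and T cell markers were higher (median 2.0). Of them 0 passed over all genes and 8 rose adjusted over the list alone (camera adjusted p = 0.000236; 0.56 with an estimated correlation), but the adjusted p was 0.26 without libraries 1 and 4. In calcium and mineral transport 2 of 17 fell, the epithelial calcium channel gene Trpv6 (-0.96) and the calcium pump gene Atp2b1 (-0.64), as did 2 adjusted over the list alone (adjusted p = 0.0289; 0.56 with an estimated correlation; 0.184 without libraries 1 and 4). Imprinted genes were lower by median (-0.32 over 32 genes), while the matrix proteoglycan gene Dcn rose (3.25; adjusted p for the list 0.0414; 0.56 with an estimated correlation; 0.287 without libraries 1 and 4). In src2ko libraries 1 to 4 the mean log2 CPM of the calcium list was 5.11, 5.25, 5.63 and 5.32 (wt mean 5.78). That of the imprinted list was 6.10, 6.17, 6.26 and 6.14 (wt mean 6.345), so these 2 lists were not low in that pair alone. Dcn stood at 278.6 and 765.5 CPM in libraries 1 and 4 and at 35.1 and 36.4 CPM in the other 2 src2ko libraries. Stroma markers did not pass and pointed 2 ways, with a median of -0.1 and a mean of 0.34: Dcn, Lum (2.68) and Fbln1 (1.30) rose and the pericyte receptor gene Pdgfrb fell by 0.88. In all, 10 of 41 lists passed with a preset correlation and 0 with an estimated correlation. Over 8 alternatives their adjusted p ran from 7.5e-17 to 0.774.

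The edgeR test gave 654 genes for src2ko against wt, 209 of them changed at least 2-fold (145 higher, 64 lower). Without src2ko libraries 1 and 4 it gave 73 (47 higher, 26 lower), 70 of them also called with all libraries. A fit of the 2 groups alone gave 45, with 11 of the 20 genes of largest change losing their call, and decidua markers as a covariate gave 145, with 8 losing it. With 1 library left out the count was 276 without src2ko library 1, 298 without src2ko library 4, 325 without wt library 3 and 388 without wt library 1. Of the 20 genes of largest change, 11 lost their call without that pair, Stac2 falling to a log2 value of 0.83 (SE 0.793 before, 0.431 after), Cxcl14 to 0.61 (0.772, 0.441) and Aspg to 0.51 (0.72, 0.531). Of the other 8 lost calls, Scand1 (3.24), Zfyve28 (-2.22) and Kcnj5 (-2.33) moved by less than their SE with all libraries. Mmp10 (2.38, SE 0.49 before and after), Mmp12 (2.19), Pappa (1.53) and Cma1 fell by more than that SE, and Il23r (-2.89) moved further from 0 by more than that SE. These 8 stood at adjusted p values between 0.0523 and 0.275. Of the 20 genes, 6 kept their call under each of the 34 alternatives that tested them: Ceacam-ps1, Il21r, Ube2ql1, Chn1os3, Ncoa2 and Htr1d. Over those alternatives the adjusted p of the 20 genes ran from 3.16e-50 to 0.778. Leaving out 1 library ended the call of Scand1 for 13 of the 16 libraries, Aspg for 12, Cxcl14 for 6, Pappa for 4, Stac2 for 2 (wt library 3 and src2ko library 4) and Kcnj5 for 2 (wt library 2 and src2ko library 4). Scaling by library totals or TPM totals shifted the median of all genes by -0.14 and -0.21 and turned the balance of calls, from 71.3% higher to 31.1% and 16.6%. Libraries of src2ko and wt did not overlap for 1458 genes, 9.69% of those tested, where chance gives 2.86%.

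Between dko and wt 122 genes differed, 36 higher and 86 lower in dko. Ceacam-ps1 fell from 72.4 ± 28.0 CPM in wt to 2.02 ± 1.3 CPM in dko (n = 4), Htr1d from 29.7 ± 10.9 to 2.0 ± 0.68 CPM. Il21r fell from 18.8 ± 8.56 to 1.64 ± 0.32 CPM and Chn1os3 from 18.6 ± 6.7 to 1.76 ± 0.315 CPM. The abundant transcripts of Doxl2, a gene of the diamine oxidase family (chromosome 6, 48974963 to 48978746), fell from 2118 ± 971 to 199.6 ± 143.0 CPM. Ceacam15, a glycoprotein gene next to Ceacam-ps1 (chromosome 7, 16671331 to 16675705), fell from 170.7 ± 50.6 to 23.7 ± 10.6 CPM. Prl7a2 rose from 953.2 ± 330.0 to 3193 ± 557 CPM and Mmp12 from 6.41 ± 3.76 to 49.7 ± 4.44 CPM. Spag5, a mitotic spindle gene (chromosome 11, 78301529 to 78322457), rose from 5.36 ± 1.59 to 17.9 ± 3.14 CPM.

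Within the same limits of CPM and overlap, the log2 fold changes of the largest falls in dko were -5.17 for Ceacam-ps1 (SE 0.499, adjusted p = 0.000118), -3.89 for Htr1d (SE 0.386, adjusted p = 0.000118), -3.51 for Il21r (SE 0.394, adjusted p = 0.000463), -3.41 for Doxl2 (adjusted p = 0.0126) and -3.39 for Chn1os3 (SE 0.309, adjusted p = 8.51e-05). Wnt10b (-3.33), the sulfotransferase gene Chst5 (-3.26), Il23r (-3.18), Ceacam15 (-2.85) and Ube2ql1 (-2.80) followed, at adjusted p values of 0.0147, 0.00456, 0.00456, 0.00288 and 0.00177. The largest rises within these limits were Mmp12 (2.96, SE 0.483, adjusted p = 0.00849), Mmp10 (2.92, SE 0.488, adjusted p = 0.0103), the transcription cofactor gene Eya1 (1.76, SE 0.266, adjusted p = 0.00456), Prl7a2 (1.74, SE 0.225, adjusted p = 0.00177) and Spag5 (1.73, SE 0.24, adjusted p = 0.00263). Rgag4 (1.52), the Rac exchange factor gene Prex2 (1.48), Ptger3 (1.46), Rbfox3 (1.18) and Vash2, a vasohibin gene (1.16), followed. Eya1 (chromosome 1, 14168954 to 14310235) and Prex2 lie within 10 Mb of Ncoa2. Because Ceacam-ps1 and Ceacam15 belong to a family of close copies, the split of reads between members is uncertain.

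**Figure D3:**
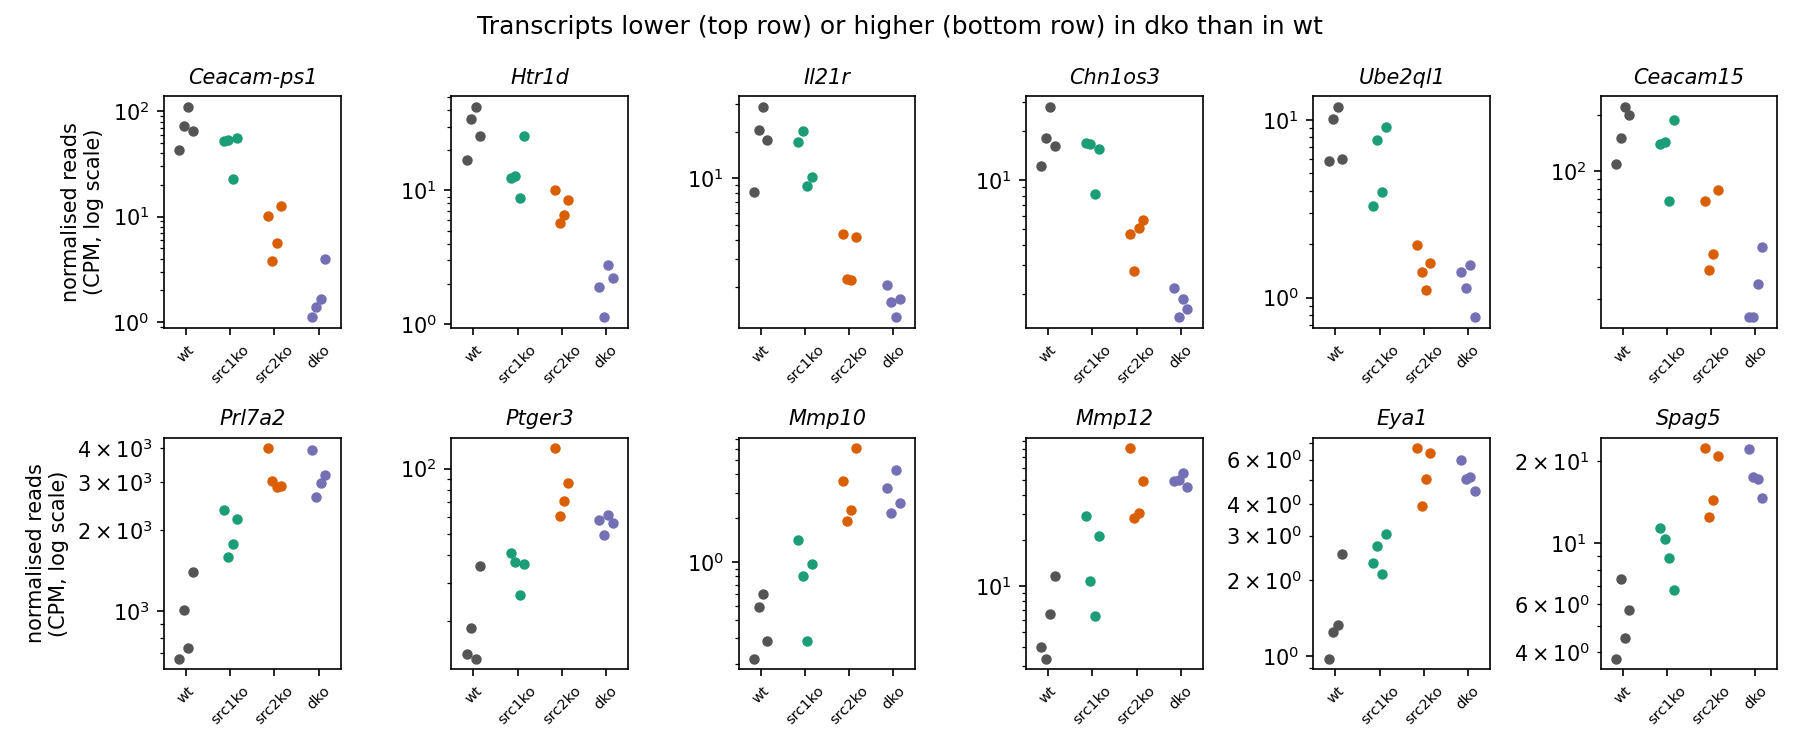
Normalised reads (CPM, log scale) of 12 genes in each of the 16 libraries by genotype; points are libraries. Ceacam-ps1, Htr1d, Il21r, Chn1os3, Ube2ql1 and Ceacam15 are lower, and Prl7a2, Ptger3, Mmp10, Mmp12, Eya1 and Spag5 higher, in dko than in wt at an adjusted p below 0.05.

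Ribosomal protein genes, parts of the translation machinery, were lower in dko than in wt for 28 of 29 members (median log2 fold change -0.24). Of them 0 fell over all genes and 3 adjusted over the list alone (camera adjusted p = 5.68e-10, or 0.51 with an estimated correlation). The mean log2 CPM of this list was 7.633, 7.693, 7.679 and 7.27 in wt libraries 1 to 4. In dko it was 7.24, 7.446, 7.352 and 7.257, so wt library 4 lay within the dko range. Stroma and pericyte markers were higher (median 0.58). Of 15, 2 rose, the matrix gene Postn (1.14, adjusted p = 0.00681) and the mural cell receptor gene Notch3 (1.02, adjusted p = 0.029). Adjusted over the list alone 5 rose (adjusted p = 1.64e-07; 0.18 with an estimated correlation). Of 27 extracellular matrix genes 25 were higher (median 0.39) and 1, Postn, rose over all genes and adjusted over the list alone (adjusted p = 5.1e-06, or 0.51 with an estimated correlation). The mean log2 CPM of this list was 6.295, 7.151, 6.888 and 6.473 in dko libraries 1 to 4. In wt it was 6.281, 6.306, 6.093 and 6.416, so dko libraries 2 and 3 carried most of the shift. Macrophage markers had a median of 0.68 with 0 of 16 passing and 1 rising adjusted over the list alone (adjusted p = 7.63e-06; 0.27 with an estimated correlation). Natural killer and T cell markers had a median of 1.4 with 0 of 8 passing either way (adjusted p = 0.00106; 0.51 with an estimated correlation). Of 13 giant cell markers Prl5a1 fell by 2.47, 12 did not pass, and 1 rose and 1 fell adjusted over the list alone (adjusted p = 0.0207; 0.51 with an estimated correlation). Immediate early genes were lower (median -0.28), with 0 of 20 passing and 3 falling adjusted over the list alone (adjusted p = 0.00268; 0.51 with an estimated correlation). Labour-associated genes were higher (median 0.24), with 0 of 12 passing and 3 rising adjusted over the list alone (adjusted p = 0.0266; 0.51 with an estimated correlation, and 0.27 with no filter on low counts). Other lists passed beside these. Endothelial markers (15 of 18 higher, median 0.21), erythroid markers (all 13 higher, 0.48), angiogenesis regulators (15 of 21 higher, 0.29) and interferon response genes (17 of 22 higher, 0.18) had 0 members passing either way (adjusted p = 0.00187, 0.00771, 0.0126 and 0.0207; 0.60, 0.60, 0.51 and 0.75 with an estimated correlation). Proliferation genes (19 of 24 higher, median 0.18) and inflammatory genes (11 of 18 higher, 0.32) had 0 passing, with 1 and 4 rising adjusted over the list alone (adjusted p = 0.00106 and 0.0132; 0.51 for both with an estimated correlation). Of 7 neutrophil markers Ngp rose (3.03), with 2 rising adjusted over the list alone (adjusted p = 0.0126; 0.51 with an estimated correlation). Mitochondrial transcripts were lower for 11 of 13 (median -0.25), with 0 passing and 1 falling adjusted over the list alone (adjusted p = 0.0207; 0.74 with an estimated correlation). The lists that led in src2ko did not pass in dko. Of 20 glycoprotein genes 0 rose and 2 fell, Ceacam15 and Psg22 (-1.60, chosen after its values were seen), with 3 rising and 2 falling adjusted over the list alone. The prolactin family split into 1 rise (Prl7a2) and 1 fall (Prl5a1) among 23, its median of -0.044 and mean of 0.012 differing in sign, and 6 rose and 2 fell adjusted over the list alone. Of 15 spongiotrophoblast markers 0 passed over all genes, and 3 rose and 1 fell adjusted over the list alone. Of 41 lists 16 passed with a preset correlation and 0 with an estimated correlation. Over 8 alternatives the adjusted p of the 16 ran from 1.83e-11 to 0.752.

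**Figure D4:**
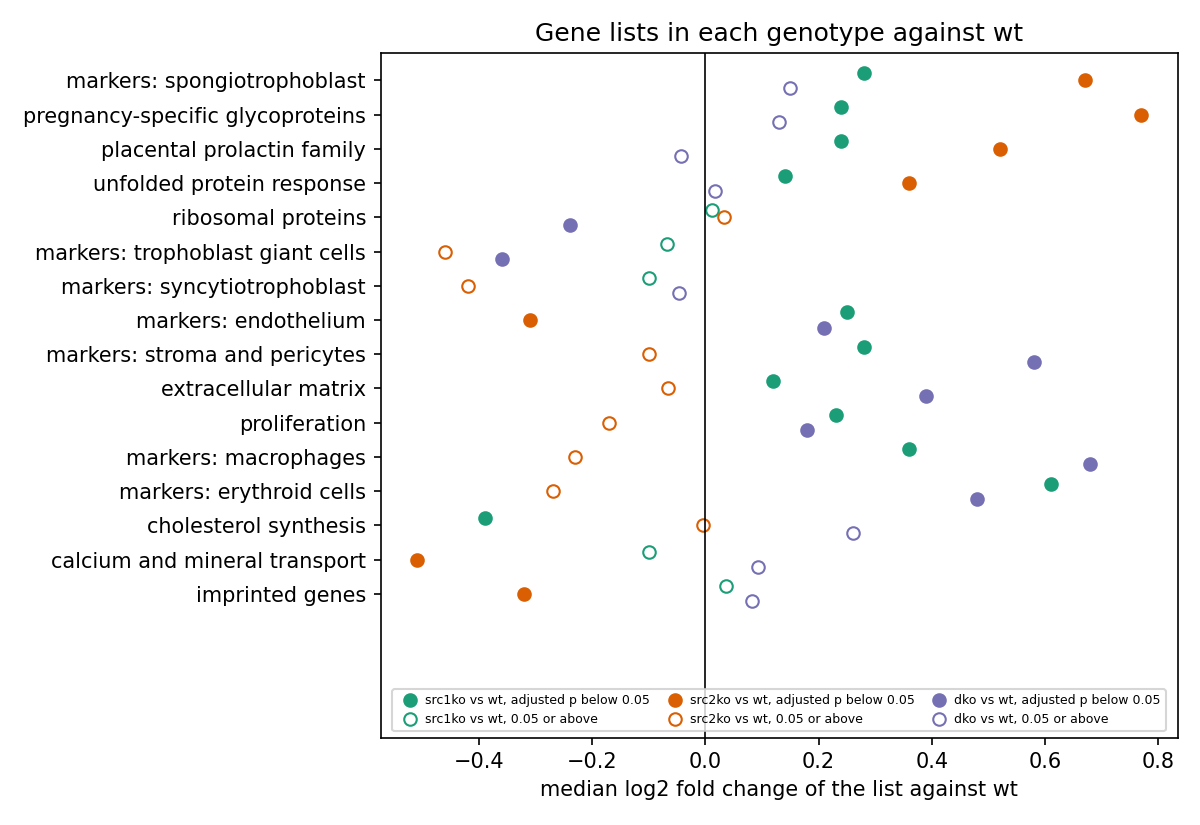
Median log2 fold change against wt (horizontal axis) of 16 gene lists for src1ko, src2ko and dko; each point is 1 list in 1 comparison, filled where the camera adjusted p with a preset correlation is below 0.05. None of the filled points passes with an estimated correlation, and none changes direction under library totals or TPM totals.

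The edgeR test gave 122 genes for dko against wt, 85 of them changed at least 2-fold (21 higher, 64 lower). Library weights, fitted with limma in place of edgeR, gave 807, DESeq2 425 and a mean of at least 5 CPM 67. The count was 47 without wt library 3, 75 without wt library 2 and 391 without wt library 4, and 49, 62, 55 and 71 without dko libraries 1, 2, 3 and 4. Without src2ko libraries 1 and 4, which enter the shared estimate of spread, it was 227 with 121 of the 122 kept. Of the 20 genes of largest change 13 kept their call under each of the 34 alternatives that tested them, and 7 lost it when 1 library was left out. These were Prex2 for 13 of the 16 libraries, Rbfox3 for 11, Rgag4 and Ptger3 for 6 each, Wnt10b for 3 (dko libraries 1, 3 and 4), Doxl2 for 1 (dko library 1) and Vash2 for 1 (wt library 3). Over the alternatives the adjusted p of the 20 genes ran from 1.82e-30 to 0.168.

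Between dko and src1ko, genotypes that differ in SRC-2, 40 genes were called, 2 higher and 38 lower in dko. Ceacam-ps1 stood at 46.2 ± 15.7 CPM in src1ko and 2.02 ± 1.3 CPM in dko, a log2 fold change of -4.52 (adjusted p = 0.000422, n = 4). Wnt10b (-3.64, adjusted p = 0.0173), Il21r (-3.10, adjusted p = 0.0024), Doxl2 (-3.04, adjusted p = 0.0412) and Chn1os3 (-3.01, adjusted p = 0.000248) fell as well. The rises were the small GTPase gene Rab30 (0.96, adjusted p = 0.0491) and 1700047I17Rik2 (0.78, adjusted p = 0.0309). All 29 ribosomal protein genes were lower in dko (median -0.27). Of them 0 passed over all genes and 13 fell adjusted over the list alone (camera adjusted p = 8.98e-15; 0.56 with an estimated correlation). Cholesterol synthesis genes were higher (median 0.83), with 0 of 24 passing and 3 rising adjusted over the list alone (adjusted p = 7.88e-10; 0.66 with an estimated correlation). Yolk sac markers were higher too (median 2.7, 0 of 21 passing either way, adjusted p = 6.46e-05; 0.75 with an estimated correlation). Of the giant cell markers Prl5a1 fell by 2.09. Immediate early genes had a median of -0.3, with 0 of 20 passing and 7 falling adjusted over the list alone (adjusted p = 9.64e-06; 0.49 with an estimated correlation). Stroma markers (12 of 15 higher, median 0.41) had 1 rising adjusted over the list alone, and macrophage (13 of 16 higher, 0.28) and natural killer and T cell markers (7 of 8 higher, 1.5) had 0 passing either way (adjusted p = 0.000271, 0.0313 and 0.000407; 0.55, 0.66 and 0.66 with an estimated correlation). In the edgeR test the count was 9, 6, 7 and 13 without dko libraries 1, 2, 3 and 4, and 7 and 10 without src1ko libraries 2 and 4. Of the 7 named genes 3, Ceacam-ps1, Il21r and Chn1os3, kept their call under all alternatives. Leaving out 1 library ended the call of Rab30 and Doxl2 for 11 of the 16 libraries, 1700047I17Rik2 for 9 and Wnt10b for 5. In all 11 lists passed with a preset correlation, their adjusted p running from 1.82e-16 to 0.747 over 8 alternatives.

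Between dko and src2ko, genotypes that differ in SRC-1, 1250 genes passed, 482 higher and 768 lower in dko. Among genes with at least 2 CPM and no overlap between libraries, the largest rises were Lpar4, a lysophosphatidic acid receptor gene (2.2 ± 1.07 CPM in src2ko, 12.6 ± 2.31 CPM in dko, log2 fold change 2.51, adjusted p = 0.00769), the matrix protease gene Adamts12 (2.44), the collagen genes Col11a1 (2.38) and Col8a1 (2.02) and the GABA transporter gene Slc6a13 (2.06). Within these limits the largest falls were the diamine oxidase gene Aoc1 (63.2 ± 59.0 to 13.04 ± 4.85 CPM, -2.28, adjusted p = 0.0254), the keratin gene Krt78 (-2.10), Htr1d (-1.94), the melanin-concentrating hormone receptor gene Mchr1 (-1.93) and the zinc transporter gene Slc30a3 (-1.82), which overlaps Dnajc5g. Of 20 glycoprotein genes 2 fell, Ceacam11 (-0.87) and Psg21 (-0.80), or 14 adjusted over the list alone, and of 20 unfolded protein response genes 8 fell and 10 adjusted over the list alone (camera adjusted p = 3.02e-07 and 1.82e-06; 0.42 for both with an estimated correlation). Of 24 proliferation genes 7 rose and 1 fell (Rrm2, -1.75), or 15 and 1 adjusted over the list alone (adjusted p = 2.57e-05; 0.25 with an estimated correlation). Of 27 extracellular matrix genes 7 rose, or 8 adjusted over the list alone (adjusted p = 2.57e-05; 0.42 with an estimated correlation). Markers of several cell types moved with them. All 18 endothelial markers were higher and 3 rose, Tek (0.97), Tie1 (0.75) and Robo4, with 6 rising adjusted over the list alone (adjusted p = 1.28e-06; 0.42 with an estimated correlation). Of 16 macrophage markers 6 rose and 2 fell, Cd68 (-0.96) and Csf1r (-0.62, chosen after its values were seen), or 11 and 2 adjusted over the list alone (adjusted p = 0.000111; 0.25 with an estimated correlation). Of 13 erythroid markers 12 were higher and 1 rose, Sptb (1.35), also adjusted over the list alone (adjusted p = 0.0152; 0.72 with an estimated correlation). The gene calls of this comparison depended on src2ko libraries 1 and 4, which hold the most Prl8a2, more than the folds did. Without them the edgeR test gave 2 genes, Fkbp11 and Rnaset2b, both lower and both chosen after their values were seen (log2 values of -0.91 and -1.21 with all libraries), and all 10 genes of largest change lost their call. For 8 of these the fold moved by less than its SE, as for Lpar4 (2.15, SE 0.455, adjusted p = 0.0911), Adamts12 (2.17), Col11a1 (2.11), Krt78 (-1.88) and Mchr1 (-2.04), while Aoc1 went to -0.59 (SE 0.561 before, 0.393 after) and Slc30a3 to -1.30. These 10 were ranked among genes without overlap between libraries, which favours folds that hold. Over the 1237 genes tested again and lost, 650 moved by less than their SE. Their median log2 value in the direction of the call went from 0.67 to 0.50 over all 1237 and the median SE from 0.159 to 0.175. The count was 393 and 389 without src2ko library 1 or 4 alone, and 554, 540, 398 and 703 without dko libraries 1, 2, 3 and 4. With Y-linked genes as a covariate it was 600, and 687 in a fit of the 2 groups alone. Scaling by library totals or TPM totals turned the balance from 38.6% higher to 80.3% and 90.5%.

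Between the single knockouts, src2ko and src1ko, 371 genes differed, 204 higher and 167 lower in src2ko. Dio2, which encodes the enzyme that activates thyroid hormone, had the largest rise among genes with at least 2 CPM and no overlap between libraries (0.21 ± 0.0582 CPM in src1ko, 3.07 ± 3.23 CPM in src2ko, log2 fold change 3.82, adjusted p = 0.0416), followed by Kcnq2 (2.22), Mmp10 (1.98), AU019990 (1.92) and Cma1 (1.69). Dio2 stood at 4.51 and 6.95 CPM in src2ko libraries 1 and 4 and at 0.405 and 0.428 CPM in the other 2, and was too low to be tested without that pair. Wnt10b (-3.09), Ceacam-ps1 (-2.53), Zfyve28 (-2.16), Il21r (-2.12) and Ncoa2 (-2.03) had the largest falls within these limits. Of 24 proliferation genes 3 fell, Mki67 (-1.26), Aurka (-0.77) and Top2a (-0.94), with 1 rising and 13 falling adjusted over the list alone (camera adjusted p = 1.29e-06; 0.45 with an estimated correlation). Of 18 endothelial markers, all of them lower, 1 fell (Tek, -0.77) and 5 adjusted over the list alone (adjusted p = 9.4e-07; 0.53 with an estimated correlation). Of the glycoprotein genes 0 passed and 8 rose and 1 fell adjusted over the list alone (adjusted p = 2.3e-05; 0.53 with an estimated correlation). Other lists moved as well. Of 16 macrophage markers Cd68 (1.19) and Csf1r (0.66) rose and F13a1 (-1.13) and Adgre1 (-1.71) fell, or 2 and 5 adjusted over the list alone (adjusted p = 0.013; 0.53 with an estimated correlation). All 21 yolk sac markers were higher (median 2.1) and 11 of 13 erythroid markers lower (-0.86), with 0 passing either way (adjusted p = 0.000681 and 0.00376; 0.72 and 0.65 with an estimated correlation). All 8 natural killer and T cell markers were higher (median 2.1), with 0 passing and 6 rising adjusted over the list alone (adjusted p = 0.000158; 0.53 with an estimated correlation). The edgeR count was 16 (10 higher, 6 lower) without src2ko libraries 1 and 4, when 6 of the other 9 named genes lost their call: Kcnq2 (log2 value 1.84 there), Mmp10 (1.26), AU019990 (1.40), Cma1 (1.17), Zfyve28 (-1.87) and Il21r (-2.65), at adjusted p values between 0.0564 and 0.338. The count was 77, 578 and 70 without src2ko libraries 1, 3 and 4. It was 54 with Y-linked genes, high in 3 src2ko libraries and 1 src1ko library, as a covariate, 106 with decidua markers as a covariate and 4 in a fit of the 2 groups alone. It was 101, 115 and 102 without src1ko libraries 1, 2 and 3, and 238 without dko library 4. Under library totals and TPM totals the share of rises went from 55.0% to 17.6% and 11.8%.

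The interaction asks whether the effect of losing SRC-2 differed with and without SRC-1, and 27 genes passed, 1 with a larger and 26 with a smaller value where SRC-1 was missing. Scaling by library totals or TPM totals, which shifted the median of all genes by 0.16 and 0.27, left 4 genes (2 larger, 2 smaller) and 1 gene (larger). Galnt6, a gene that starts O-linked glycan chains, stood at 47.5 ± 10.8 CPM in wt and 182.4 ± 36.6 CPM in src2ko but at 56.7 ± 10.7 CPM in src1ko and 75.4 ± 17.9 CPM in dko (interaction log2 value -1.53, adjusted p = 0.0473, n = 4). Nab2, a corepressor gene (-1.43), Cilp2 (-1.42), Dtx1, a Notch pathway gene (-1.20), and Pdlim4 (-1.19) had the same sign, and Psd3 the opposite one (0.83, adjusted p = 0.034), with 22.4 ± 0.871 CPM in src2ko against 33.9 ± 2.2 CPM in wt. Nab2 overlaps Stat6 and Nemp1, and Galnt6 overlaps Galnt6os. All 15 spongiotrophoblast markers, all 20 glycoprotein genes and all 23 prolactin genes had values below 0 (medians -0.89, -0.86 and -0.87). Of each list 0 passed over all genes, and 11, 10 and 0 fell adjusted over the list alone (camera adjusted p = 3.35e-10, 1.02e-10 and 6.96e-07; 0.4 for each with an estimated correlation). The unfolded protein response had a median of -0.57, with 0 of 20 passing and 9 falling adjusted over the list alone (adjusted p = 1.29e-08; 0.4 with an estimated correlation). Lists tied to tissue make-up moved in the same contrast with 0 members passing either way: all 21 yolk sac markers were above 0 (median 3.4, adjusted p = 7.66e-05), as were 21 of 24 cholesterol synthesis genes (0.86, adjusted p = 0.000153) and 16 of 18 endothelial markers (0.29, adjusted p = 0.0182; 0.75 for each of the 3 with an estimated correlation). All 29 ribosomal protein genes were below 0 (median -0.30, adjusted p = 5.62e-07; 0.7 with an estimated correlation). With all libraries 2649 genes stood at an unadjusted p below 0.05, and DESeq2 called 423. Without src2ko libraries 1 and 4 the edgeR test gave 0 interaction genes, and all 6 genes named here lost their call with values of 0.83 (Psd3), -1.24 (Galnt6), -1.25 (Nab2), -1.38 (Cilp2), -0.90 (Dtx1) and -0.97 (Pdlim4), the first 4 within their SE of the value with all libraries. With 1 library left out it was 0 without dko library 3 or 4, 2 without wt library 3 or src1ko library 2 or 4, 3 without src1ko or src2ko library 1, 4 without dko library 1 and 5 without wt library 1, src2ko library 4 or dko library 2. It was 9 without src1ko library 3, 41 without src2ko library 2, 45 without wt library 2 and 68 without src2ko library 3.

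**Figure D5:**
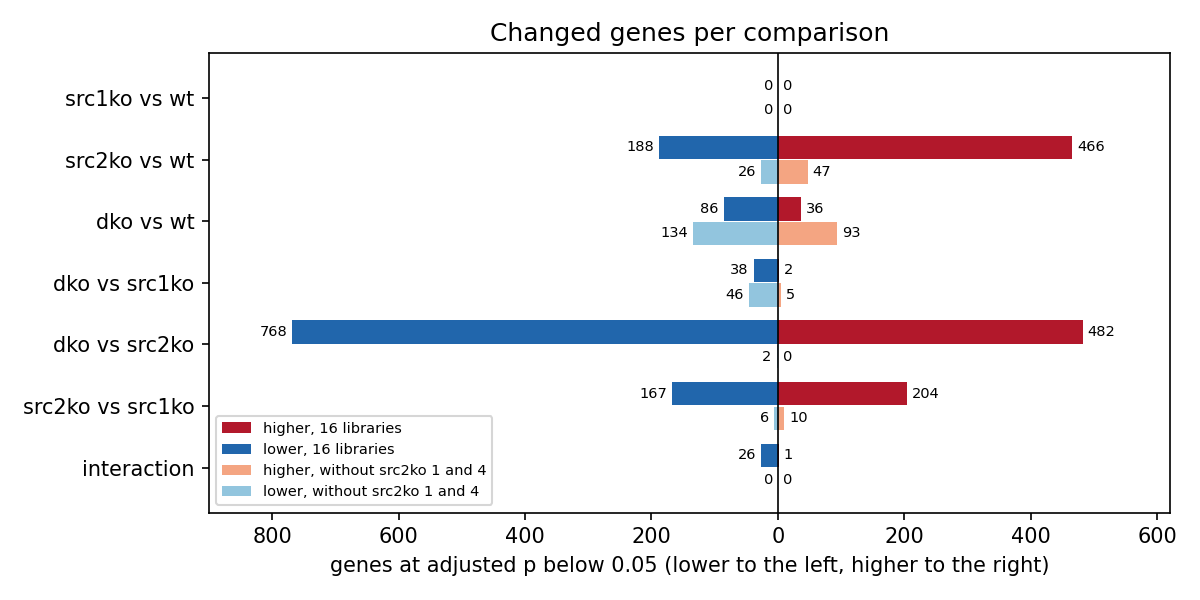
Genes at an adjusted p below 0.05 in the edgeR test for each comparison, higher to the right and lower to the left (number of genes, horizontal axis), with all 16 libraries and without src2ko libraries 1 and 4. The src2ko against wt count goes from 654 to 73 and the dko against src2ko count from 1250 to 2.

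Genes called in both src2ko and dko against wt moved the same way. Both comparisons shared 25 rises and 35 falls, with 0 genes in opposite directions, where independent lists of these sizes share 1.1 rises and 1.1 falls. Shared falls included Ceacam-ps1, Il21r, Htr1d, Chn1os3, Ube2ql1 and Wnt10b, and shared rises Prl7a2, Ptger3, Mmp10, Mmp12, Kcnq2 and Eya1. Across all genes, which are not independent replicates, the fold changes of src2ko and dko correlated at r = 0.40, below the 0.50 (0.46 to 0.54) that the shared wt libraries alone gave in 20 simulations. The covariance was 0.0831 against a simulated 0.0477. Each gene was drawn independently in these simulations. Neither their range of r nor their covariance therefore takes in shifts shared by many genes, such as those of tissue make-up. With the wt libraries split into separate pairs the mean r was 0.15 (0.047 to 0.34 over 6 ways) and between 12 and 33 genes were shared. In comparisons that share no library, src2ko against wt and dko against src1ko, 20 falls were shared where independent lists share 0.47, and 1 rise where they share 0.062, while r was 0.021. For src1ko the covariance was 0.0782 with src2ko and 0.0695 with dko, against 0.0474 and 0.0469 from the same simulations. The correlations were r = 0.38 and 0.40 (simulated 0.49 for both). With the wt libraries split, their means were 0.12 (-0.13 to 0.23 over 6 ways) and 0.11 (-0.19 to 0.35), ranges that span 0.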

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

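The tests of genes called again or lost without src2ko libraries 1 and 4 and of their folds, of placental marker lists against the falls in dko, of the direction in src2ko against src1ko and of the yolk sac genes moving together were chosen only after the result was seen; the test with Y-linked genes, the count near the targeted genes, the cholesterol relation and the splits were planned.

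Most of the 654 genes of src2ko against wt lost their call without src2ko libraries 1 and 4. This pair held the most of the decidual hormone transcript Prl8a2, at 165 and 928 CPM against at most 58.9 CPM in the other 14 libraries. Erv3 (121 and 563 against at most 57.4 CPM) and Tfpi2 (141 and 637 against at most 46.4 CPM) were highest in the same pair. Both were chosen after their values were seen and are not separate evidence of decidual tissue. Against an uneven number of male fetuses as the whole cause stand 496 genes with Y-linked genes as a covariate, and against maternal decidual tissue in that pair as the whole cause stand 70 of the 654 genes called again without it. For the genes that were lost, more decidual tissue in the pair may be part of the cause, since leaving it out gave 73 genes, leaving out libraries 2 and 3 gave 2269 (606 of the 654 among them) and leaving out any of the other 4 pairs gave 163 to 272; with 2 libraries left out each time, the number of libraries alone does not explain the 73. For the 575 genes tested again and lost, the median log2 value in the direction of the call went from 0.69 to 0.49 and the median SE from 0.154 to 0.159, so most calls ended with a smaller fold and not with none. Of the 16 decidua markers tested 3 stand in another list and 14 reach 1 CPM in the library with the lowest mean, so the list is no clean measure of maternal cells, and the SRC-2 genotype itself stays open as a cause of the decidual content or of the lost genes and was not tested.

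Of the 86 genes lower in dko than in wt, sequence carried along from the strain of the targeting around Ncoa2 and Ncoa1 is argued against as the whole cause: with Ncoa1 and Ncoa2 left aside, 2 of the 82 genes with a known position (2.4%) lie within 10 Mb of these genes. A smaller share of spongiotrophoblast, glycogen trophoblast, giant cells or syncytiotrophoblast is not decided by the marker lists. The lowest median of these 4 marker lists was -0.36 (giant cells), beside a median fall of -1.52. The genes called lower were selected for falling, which widens that gap by itself. The giant cell list also passed as lower (camera adjusted p = 0.0207, or 0.51 with an estimated correlation). Loss of SRC-2 in either background is a candidate explanation: 81% of the 84 genes left were lower in src2ko than in src1ko, libraries that the dko comparison does not use, against 49.5% of all genes, and 90.5% were without src2ko libraries 1 and 4. Beside the median of -1.52 in dko against wt, these genes had medians of -0.72 in src2ko against wt, -1.32 in dko against src1ko (34 called lower) and -0.25 in src1ko against wt, all 3 of which share libraries with the dko comparison. Shared litters, a change in a cell type, whether or not a list covers it, and an added effect of SRC-1 stay open.

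Cholesterol synthesis genes were lower in src1ko than in wt by point estimate, with 0 of 24 passing and a list adjusted p of 0.55 with an estimated correlation. Within groups the mean of these genes rose with that of the yolk sac list over the 16 libraries (r = 0.886, permutation p = 0.00224, adjusted over 8 relations 0.0179; rho = 0.90, p = 0.00086, adjusted 0.00688; r = 0.808 without dko libraries 1 and 2). The yolk sac genes moved together, with a median correlation of 0.985 of each with the mean of the others and 0.993 for the 6 most abundant, and Afp ran from 27.4 to 20830 CPM, so more yolk sac tissue left on the wt placentas is a candidate explanation for the lower cholesterol genes of src1ko. No yolk sac marker stands in another list and 8 of 21 reach 1 CPM in dko library 1, the lowest, so low levels may come from placenta. An effect of SRC-1 on sterol synthesis, or on the yolk sac itself, stays open and was not tested.

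Splits of the libraries argue against chance as the source of the counts of called genes but do not exclude it. The counts were 654 genes for src2ko against wt (at most 6 in any other of the 35 splits of the 8 libraries) and 122 for dko against wt (at most 1). They were 40 for dko against src1ko (at most 0), 1250 for dko against src2ko (at most 1) and 371 for src2ko against src1ko (at most 10). In each of these 1 of the 35 splits, the real one, gave as many genes, and for the interaction 1 of 100 drawn splits did (27 genes, at most 4 in another). A share of 1 in 35 is the smallest these splits can give, and the other splits mix genotypes. No split can tell genotype from shared litters or tissue make-up. For src1ko against wt, where edgeR gave 0 genes, every one of the 35 splits must give at least as many (the highest other gave 1), so the count of splits says nothing about chance.

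The effect of losing SRC-2 differed with and without SRC-1 for 27 genes by the test of the difference itself. Those named were Psd3 (0.83), Galnt6 (-1.53), Nab2 (-1.43), Cilp2 (-1.42), Dtx1 (-1.20) and Pdlim4 (-1.19), and without src2ko libraries 1 and 4 the test gave 0 genes, with values of 0.83, -1.24, -1.25, -1.38, -0.90 and -0.97 in the same order. The count was 4 (2 higher, 2 lower) with library totals, 1 (higher) with TPM totals, and 2 with the replicate block or with the decidua covariate, so it depends on these settings.

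In 44 of 500 groups of 4 libraries, 1 library stood far from the other 3: its gap to the nearest, divided by the range of the group, exceeded the 95% critical value of Dixon's test for 4 values. Chance sets apart about 1 in 20 groups, 25.0 here. Levels are in CPM, or mean log2 CPM for marker lists, each with the range of the other 3 libraries and that ratio. In wt library 1, these were 1700047I17Rik2 2.985 (others 2.535 to 2.592, 0.873), Erv3 19.59 (others 1.031 to 3.341, 0.876), Hspb7 2.768 (others 0.9793 to 1.206, 0.873), Prl2c5 452.3 (others 661.6 to 695.4, 0.861), Slc30a3 21.28 (others 36.06 to 37.74, 0.898), the mean of the giant cell markers 8.77 (others 9.25 to 9.30, 0.909) and the mean of the decidua markers 3.69 (others 3.05 to 3.07, 0.973). In wt library 3, it was Col11a1 0.3617 (others 1.031 to 1.139, 0.861). In wt library 4, it was Adamts12 1.901 (others 0.7234 to 0.9224, 0.831). In src1ko library 1, these were Rbfox3 3.806 (others 2.206 to 2.451, 0.847), Tek 48.47 (others 33 to 34.73, 0.888) and Tie1 87.26 (others 51.13 to 55.33, 0.884). In src1ko library 3, these were Ceacam-ps1 22.83 (others 52.43 to 56.11, 0.889), Chn1os3 8.197 (others 15.39 to 16.86, 0.83), Erv3 0.797 (others 12.37 to 13.11, 0.94), Pdlim4 28.06 (others 30.89 to 31.34, 0.863), Stac2 0.5123 (others 1.374 to 1.482, 0.889), Xist 1.252 (others 916.5 to 1019, 0.899) and the mean of the smooth muscle markers 3.44 (others 3.92 to 4.01, 0.852). In src1ko library 4, these were 1700047I17Rik2 1.753 (others 1.956 to 1.995, 0.839), Ceacam11 11240 (others 8707 to 8969, 0.897), Doxl2 3218 (others 896.7 to 1272, 0.838), Prl4a1 30.71 (others 15.77 to 17.28, 0.899), Scand1 3.281 (others 0.3989 to 0.797, 0.862) and the mean of the syncytiotrophoblast markers 5.61 (others 6.52 to 6.61, 0.916). In src2ko library 1, these were AU019990 11.7 (others 4.34 to 5.016, 0.908), Adgre1 1.377 (others 0.9066 to 0.9249, 0.961), Prex2 115.1 (others 56.67 to 62.61, 0.898), Prl7a2 4000 (others 2879 to 3021, 0.873) and Psg21 32390 (others 19480 to 21640, 0.833). In src2ko library 2, it was Ncoa1 10.81 (others 7.071 to 7.65, 0.845). In src2ko library 3, these were Corin 14.67 (others 7.803 to 7.92, 0.983), Lpar4 3.79 (others 1.53 to 1.908, 0.833) and Xist 860.4 (others 3.989 to 94.83, 0.894). In src2ko library 4, it was Cxcl14 22.79 (others 1.33 to 4.208, 0.866). In dko library 1, it was the mean of the syncytiotrophoblast markers 6.85 (others 6.18 to 6.25, 0.902). In dko library 2, these were Atp2b1 206.5 (others 268.7 to 278.9, 0.859), Ceacam11 6504 (others 9020 to 9490, 0.843), Ceacam13 616.4 (others 972.9 to 1015, 0.894), Chn1 3.692 (others 2.54 to 2.714, 0.849), Cilp2 3.949 (others 5.427 to 5.595, 0.898), Csf1r 852.7 (others 975.9 to 980.1, 0.967), Psg18 1886 (others 2602 to 2649, 0.938) and Tie1 81.38 (others 59.44 to 59.92, 0.978). No explanation was tested for them beyond those weighed here.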

How the results depend on the processing

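DESeq2, the yolk sac covariate, comparisons sharing no library, and leaving out src2ko libraries 1 and 4 were tried only after the data had been seen. Median-of-ratios size factors and limma-trend with a pseudocount of 1 were parts of the planned main test that became alternatives after its replacement. The other alternatives were planned. The counts of changed genes moved by more than 1.5 times under the settings given in this part, each against the main count of 654 for src2ko against wt, 122 for dko against wt, 40 for dko against src1ko, 1250 for dko against src2ko, 371 for src2ko against src1ko and 27 for the interaction; under all other settings they stayed within 1.5 times, and src1ko against wt stayed at 0 except under DESeq2, which called 1. Library totals gave 991 for src2ko against wt, 778 for src2ko against src1ko and 4 for the interaction. TPM totals gave 1802, 1027 and 1 for these and 3006 for dko against src2ko. With quantile normalization the interaction gave 8, and with median-of-ratios size factors 17. Without a filter on low counts dko against src2ko gave 715, src2ko against src1ko 238 and the interaction 4. A mean of at least 5 CPM gave 67 for dko against wt and 26 for dko against src1ko. Library weights, fitted with limma in place of edgeR, gave 413 for src2ko against wt, 807 for dko against wt and 193 for dko against src1ko. A fit of the contrasted groups alone gave 45 for src2ko against wt, 687 for dko against src2ko and 4 for src2ko against src1ko, from fewer libraries. The sex covariate gave 600, 54 and 6 for dko against src2ko, src2ko against src1ko and the interaction. The decidua covariate gave 145 for src2ko against wt, 106 for src2ko against src1ko and 2 for the interaction, and the yolk sac covariate gave 6 for the interaction. DESeq2 gave 1194, 425, 156, 1963, 1009 and 423, in the order of the main counts. Leaving out src2ko libraries 1 and 4 gave 73, 227, 2, 16 and 0 in that order without dko against src1ko, which stayed within 1.5 times at 51. A 2-fold threshold, which adds a condition, gave 209 for src2ko against wt, 330 for dko against src2ko, 123 for src2ko against src1ko and 11 for the interaction. Apart from settings that add a condition or leave out libraries, the cause was not tested. Of the named genes, Hspb7 in dko against src2ko turned from a log2 value of -3.51 to 0.89 without src2ko libraries 1 and 4.

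With 1 library left out in turn, the counts ran from 0 to 0 for src1ko against wt, 276 to 954 for src2ko against wt, 47 to 391 for dko against wt, 6 to 56 for dko against src1ko, 389 to 1640 for dko against src2ko, 70 to 578 for src2ko against src1ko and 0 to 68 for the interaction.

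The labels number the replicates of each genotype 1 to 4. Over 24 pairs of libraries with the same number, the correlation of deviations from the group means ran from -0.362 to 0.302 (mean -0.025), was over 0.1 in 8 pairs, and 3 of 16 libraries correlated best with one of their own number, so the numbers were not taken to pair the libraries. With the replicate number as a block the counts were 15 for dko against src1ko, 224 for src2ko against src1ko and 2 for the interaction, and stayed within 1.5 times elsewhere.

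Gene lists past camera's threshold went from 16, 10, 16, 11, 16, 14 and 14 (src1ko, src2ko and dko against wt, dko against src1ko, dko against src2ko, src2ko against src1ko, interaction) to 0 in each with an estimated correlation. With fry they went to 0, 0, 1, 0, 9, 1 and 0. Library totals left 6 for src2ko against wt, and no filter on low counts gave 18 for dko against src1ko. Of the 97 list calls, 97 passed with the replicate block, 96 with no filter, 86 with library totals, 84 with TPM totals, 87 with a pseudocount of 0.1, 85 without src2ko libraries 1 and 4 and 11 with fry, and 0 turned direction. With the wt libraries split, the mean correlation of fold changes went from 0.38 to 0.12 for src1ko and src2ko, from 0.40 to 0.11 for src1ko and dko, and from 0.40 to 0.15 for src2ko and dko, and the calls shared by src2ko and dko from 60 to between 12 and 33. Depth limits what can be called among rare transcripts: at the lowest depth of 15595714 reads, genes under 1 CPM in more than 12 libraries were not tested.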

Other observations

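The window of 10 Mb and the share of genes lower in dko that lie within it were planned. The Fisher exact tests of called genes near Ncoa2 and Ncoa1 were not part of that plan. The genes named here were chosen after their values were seen.

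Dkk1, Corin and Gclc were among the genes lower in both src2ko and dko than in wt. Dkk1, which encodes a secreted Wnt antagonist (chromosome 19, 30545863 to 30549665), stood at 10.4 ± 1.28 CPM in wt, 9.33 ± 2.86 CPM in src1ko, 2.9 ± 0.913 CPM in src2ko and 2.88 ± 0.399 CPM in dko (n = 4). Its log2 fold change was -1.84 in src2ko and -1.86 in dko against wt (adjusted p = 0.00118 and 0.00177), and -1.70 in dko against src1ko (adjusted p = 0.00884; 0.0619 without dko library 2). Corin, which encodes a protease that activates natriuretic peptide (chromosome 5, 72300025 to 72504473), fell from 35.1 ± 3.57 CPM in wt to 9.58 ± 3.4 CPM in src2ko and 14.7 ± 3.8 CPM in dko (-1.87 and -1.26, adjusted p = 0.000861 and 0.0135). Gclc, which encodes a subunit of the enzyme that starts glutathione synthesis (chromosome 9, 77754535 to 77794485), stood at 77.0 ± 5.91 CPM in wt, 56.3 ± 14.3 CPM in src1ko, 36.0 ± 9.59 CPM in src2ko and 27.0 ± 2.54 CPM in dko. Its log2 fold change was -1.10 in src2ko and -1.51 in dko (adjusted p = 0.00393 and 0.00123). For each of the 3 genes all 4 src2ko and all 4 dko libraries lay below all 4 wt libraries. Against wt these calls held under all 34 alternatives, with adjusted p values up to 0.0486, except for Corin in dko, which was lost without wt library 3 or dko library 1 (adjusted p up to 0.0549).

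The transcription factor gene Sox11, the hyaluronan receptor gene Cd44 and the cytokine gene Lif were lower than in wt as well. Sox11 stood at 46.0 ± 11.3 CPM in wt, 17.4 ± 11.1 CPM in src2ko and 7.32 ± 2.86 CPM in dko (-1.40 and -2.65, adjusted p = 0.0436 and 0.00389). Its call in dko held under all 34 alternatives and that in src2ko was lost under 15, 10 of them with 1 library left out. Cd44 fell from 28.4 ± 6.87 to 10.6 ± 4.78 and 8.76 ± 1.21 CPM (-1.42 and -1.70, adjusted p = 0.0323 and 0.036), and its calls were lost under 7 and 8 alternatives, 5 and 7 of them with 1 library left out. Lif fell from 3.94 ± 1.41 to 1.6 ± 0.166 and 1.53 ± 0.215 CPM (-1.29 and -1.36, adjusted p = 0.0171 and 0.0312), and its calls were lost under 5 and 9, 2 and 6 of them with 1 library left out. In dko against src1ko, Sox11 (-2.39, adjusted p = 0.0159) and Gclc (-1.06, adjusted p = 0.0255) passed beside Dkk1, and each lost its call under 6 alternatives. Corin (-0.93), Cd44 (-1.35) and Lif (-1.23) did not pass there (adjusted p = 0.123, 0.164 and 0.0974). In src1ko against wt 0 of these 6 genes passed, with log2 values between -0.45 (Gclc) and -0.13 (Lif). Set against src1ko directly, src2ko was lower for Dkk1, Corin and Lif (-1.68, -1.55 and -1.17, adjusted p = 0.00567, 0.00568 and 0.0401), while Gclc, Cd44 and Sox11 did not pass (adjusted p = 0.0709, 0.107 and 0.106). All 3 of these calls were lost in a fit of the 2 groups alone and without src2ko libraries 1 and 4, and that of Lif also without 10 of the 16 libraries left out in turn.

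Of the 52 tested genes within 10 Mb of Ncoa2, 4 were called in dko against wt, where the rate elsewhere gives 0.41 (Fisher exact p = 0.000765, adjusted over 12 comparisons 0.00918). They were Eya1 (1.76), Prex2 (1.48), Mcmdc2 (-2.32) and Snhg6 (-1.42). The same 4 were called in src2ko against wt, where the rate elsewhere gives 2.3 (Fisher exact p = 0.287, adjusted 0.574), at 1.85, 1.36, -2.79 and -1.27. Near Ncoa2, dko against src1ko called 1 gene, Snhg6, where the rate elsewhere gives 0.13 (Fisher exact p = 0.126, adjusted 0.402). For src2ko against src1ko it was 3 where that rate gives 1.3 (Fisher exact p = 0.134, adjusted 0.402). The call of Prex2 in dko against wt was lost with most of the libraries left out in turn. Around Ncoa1 0 of 42 genes were called in dko. Snhg6 and Mcmdc2 are neighbours, and their annotated ends overlap by position, so the Fisher tests may count 1 change as 2 calls. Strain-derived sequence around Ncoa2 may account for these 4. With Ncoa1 and Ncoa2 left aside, 2 of the 82 genes lower in dko with a known position (2.4%) lie in the windows. These are Mcmdc2 and Snhg6 themselves, so that share does not bear on the cause of the 4. A local effect of the deletion stays open, and no test separated it from strain-derived sequence.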
